A study of Drosophila melanogaster with 26 samples.

How the data were processed

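Contacts of 8 genomic loci were mapped with chromosome conformation capture on chip (4C), an assay in which crosslinked, digested and religated chromatin is opened at one chosen locus, the bait, by inverse PCR, so that the DNA ligated to it can be counted on a microarray. Per the labels, each biological replicate pooled 40 pairs of central brain hemispheres of Drosophila melanogaster third-instar larvae raised at 25 °C. The tissue was fixed for 15 min in 2% formaldehyde, cut with EcoRI, ligated, cut again with DpnII or NlaIII, circularised and amplified with 30 PCR cycles and then linearly from a T7 promoter. The 4C material carried one dye and digested genomic DNA of the wild-type strain carried the other on a custom 2-colour Agilent array. Each group had 2 biological replicates. In 7 groups replicate 1 was hybridised with 4C material in Cy5 and replicate 2 in Cy3. In the other groups (wild type Abd-B, wild type Ptx1 and inversion Abd-B) each replicate was hybridised in both orientations.

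The deposited files are scanner outputs, 1 per array. Per the file headers, the values used are intensity values of the green and red channels that Agilent Feature Extraction (version 9.5.1.1 for the wild-type Abd-B and Ptx1 arrays with a settings block, 10.1.1.1 for the others, not stated for 1 array) had background-subtracted with spatial detrending and dye-normalised with an intensity-dependent curve. The SD of the log2 dye factor over the probes of an array ran from 0.145 to 0.727. Files of 25 arrays were analysed. The dye-swapped array of inversion Abd-B replicate 1, which the labels list as sample 26, is not analysed here, so that replicate rests on 1 array and its dyes are unbalanced.

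An array held 45220 spots: 40811 genomic probes of 60 nt with a median of 1320 bp between starts, 1832 random-sequence probes, 59 lambda phage probes and 2518 control spots. Of the genomic probes, 24.4% to 61.9% per array (median 45.6%) were well above background in the 4C channel and 42.3% to 88.8% (median 54.4%) in the reference channel. Among random-sequence probes the medians were 17.1% and 18.7%, the level that needs no matching target. Saturated 4C spots numbered at most 249 per array. Per the file headers, the other columns used are flags. Spots flagged in them as non-uniform or as population outliers (median 85 per array, at most 1644) were left out. Precision is limited by the 2 replicates per group.

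Each probe's log2 ratio of 4C over reference was turned to one direction by the dyes in the labels, and the ratios of an array were centred on their median over genomic probes. The intensity-dependent dye curve of Feature Extraction was kept in these signals. No further loess or quantile step was applied, since a bait raises much of its own chromosome. Only the alternative with normexp background correction starts from signals without that curve. Probe ratios were averaged in 50 kb windows with at least 5 probes (2353 windows, median 17 probes), and arrays of one biological replicate were averaged, which gave 20 replicates in 10 groups. Coordinates are those in the files. The files do not name the genome build and were used without a gene annotation in that build, so windows are given by position and the planned tests on gene lists (Polycomb targets, the Antennapedia and bithorax complexes, ribosomal, Osi and cuticle protein genes) were not run. A bait's position is the 50 kb window in which its own maps rose most above those of the other baits.

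Windows within 500 kb of a bait were left out of its tests, and tests of one bait against the others left out windows near any bait (2207 tested). Windows were fitted with limma 3.58.1 in R 4.3.3 (with data.table in version 1.17.8), with group and dye orientation as terms, all 20 replicates sharing one variance estimate on 9 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values with a threshold of 5%, and all tests are two-sided. Adjacent passing windows formed domains. The text draws its domains from the 5 with the largest peak per bait, same arm first, and from the 5 largest rises and 5 largest falls per inversion contrast. Quantities with 1 value per bait were tested with an exact two-sided sign-flip permutation over the 8 baits (256 sign patterns, smallest p 0.0078). Region shifts were tested with limma's fry, which asks whether the windows of a region move one way on balance. Region boundaries are the labels' 5.8 Mb of 3R and 17 Mb of 3L, counted from the most centromere-proximal probe of each arm (5.80 Mb on 3R and 6.76 Mb on 3L), without windows within 500 kb of them. An exact permutation of 2 replicates against 2 cannot go below p = 0.333. The inversion tests were repeated with a replicate block, under which 14 windows rose for Abd-B. The order of replicates showed no general pairing of samples across groups: deviations of replicate 1 correlated between groups with a median r of 0.04 over 45 pairs of groups. In 13 of these pairs r was above 0.1, with a maximum of 0.28. After the dye term 2 pairs were above 0.1, with a maximum of 0.22.

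The tests and most alternatives were chosen before the data were examined. Chosen later were the region shifts centred on the other chromosomes, the comparison within array sets, the GC correction, the run without the dimmest array, the exact test of contacts among 3 bait loci, the jumps at the stated breakpoints, and leaving the bait at the tested locus out of the comparison of bait loci. Groups that share a scan day form 4 array sets: wild type Abd-B and Ptx1; Antp, wntD, CG5107 and Crc; trh, RpII140 and inversion Antp; and inversion Abd-B. Alternatives covered background correction, loess, centring, scaling between arrays, window size and summary, dim probes, the dye term, a replicate block, slide as a block, arrays as samples, the zone around a bait, the false discovery rate and leaving out replicates or baits. In data simulated at the size of the Abd-B inversion contrast, 26% of windows changed by a log2 of 1 and 96% of those changed by 2 were called. Of 126 calls 3.17% were false, and 0 windows were called with no change simulated. The simulated noise was independent between windows and replicates and held no batch. These rates therefore need not hold for the measured contrast, in which genotype goes with slide and scan day. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3).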

Results

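The data comprised genome-wide 4C maps of 8 loci of chromosome 3 in wild-type larval central brain and of 2 of these loci in the inversion In(3LR)sep. Wild-type baits were Abd-B and Antp (Hox genes of the bithorax and Antennapedia complexes), Ptx1 (a homeobox gene), trh (a bHLH-PAS transcription factor of tracheal development), wntD (a Wnt ligand), CG5107 (an uncharacterised gene), Crc (listed as Calreticulin in the labels, a chaperone of the endoplasmic reticulum) and RpII140 (a large subunit of RNA polymerase II). Abd-B, Antp, Ptx1 and trh are known targets of Polycomb, a repressive chromatin system, and the study's title names contacts among such domains as its subject. Each of the 10 groups had 2 biological replicates. Between replicates the 50 kb window values correlated across windows with r from 0.72 for inversion Antp to 0.91 for wild type trh (windows are not independent replicates). Over windows outside chromosome 3 alone, r ran lower, from 0.52 for wild type Antp to 0.83 for wild type trh.

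Each bait's position was read from its maps, as the window that rose most above the other baits, and was not checked against a gene annotation. The trh maps peaked at 3L 250001-300000, 25.9-fold above the other baits, and the wntD maps at 3R 9100001-9150000, 24.5-fold above. On 3R the other peaks were Antp at 2600001-2650000 (13.1-fold), Crc at 5450001-5500000 (11.7-fold), RpII140 at 9950001-10000000 (13.0-fold), Abd-B at 12800001-12850000 (5.32-fold), CG5107 at 21350001-21400000 (13.9-fold) and Ptx1 at 26700001-26750000 (7.23-fold). These windows were not tested.

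In wild-type brain all 8 loci contacted their own chromosome arm more than other chromosomes. Away from the bait, same-arm windows exceeded windows on other chromosomes by a mean log2 of 1.26, or 2.40-fold (SD over baits 0.38, exact sign-flip p = 0.0078, the smallest possible, adjusted 0.0117, 8 of 8 baits). The excess was lowest for Ptx1 at 0.67 ± 0.16 (SD, n = 2) and Abd-B at 0.93 ± 0.49, and highest for wntD at 1.65 ± 0.14 and Crc at 1.80 ± 0.41. For the other arm of chromosome 3 the mean difference from other chromosomes was 0.08 and missed the threshold (SD 0.13, exact p = 0.078, 6 of 8 baits above 0). Crc had the highest value there, 0.37 ± 0.11 (n = 2), and Ptx1 the lowest, -0.06 ± 0.03. The other-arm mean passed the threshold with 20 kb windows (0.10, exact p = 0.0234) and without the Ptx1 bait (0.10, exact p = 0.0312).

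Contact fell with distance along the arm. Window signal dropped by a mean log2 of 1.44 per log10 unit of distance (SD over baits 0.46, exact p = 0.0078, adjusted 0.0117, slopes below 0 for 8 of 8 baits). The slope was steepest for CG5107 at -1.82 ± 0.04 (n = 2) and RpII140 at -1.75 ± 0.03, and shallowest for Abd-B at -0.65 ± 0.10 and Ptx1 at -0.76 ± 0.05. These baits, also the lowest in same-arm excess, are the whole of one array set, so bait and set cannot be told apart here. On the inversion Abd-B arrays, of another set and with part of 3R moved away, the slope was -1.60 to -1.67 per array. Between 0.5 and 1 Mb from the bait, wntD stood 3.28 ± 0.11 above other chromosomes and Abd-B 1.69 ± 0.47. Between 10 and 20 Mb, Crc still stood 1.39 ± 0.33 above and Ptx1 0.47 ± 0.15.

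**Figure D1:**
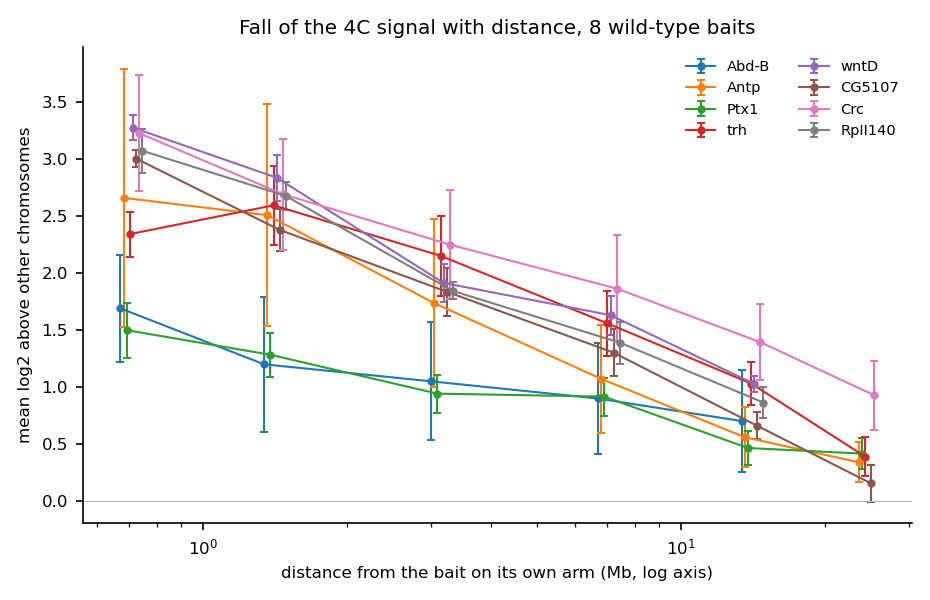
Mean log2 4C signal above that of other chromosomes (vertical axis) against distance from the bait on its own arm (horizontal log axis, Mb) for the 8 wild-type baits; points are means of 2 replicates at the middle of each distance bin, shifted slightly sideways, and bars are SDs. Abd-B at 1.69 and Ptx1 at 1.50 start lowest at 0.5 to 1 Mb, and Crc is the highest at 10 to 20 Mb with 1.39.

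Each bait was then compared with the mean of the other 7, and windows in which it stood higher are called preferred. Distance was not removed in this comparison, so a window near the bait can be preferred through nearness alone. Of 1617 windows that rose over all baits, 898 (55.5%) lay on the bait's own arm, 116 on the other arm and 603 on other chromosomes. For CG5107 and wntD 95 of 98 and 100 of 108 preferred windows lay on 3R, and for RpII140 66 of 81, with 12 on other chromosomes. Antp had 74 of 119 and Crc 167 of 264 on 3R, with another 53 of the Crc windows on 3L. The trh bait, the one bait on 3L, rose in 332 of 459 tested 3L windows (72.3%) and in 162 windows on other chromosomes. Abd-B and Ptx1 differed in placing only 20 of 124 and 44 of 327 on 3R, against 89 and 253 on other chromosomes. Other chromosomes also held more tested windows, 1321 against 427 on 3R. For Abd-B 4.68% of tested windows rose on 3R and 6.74% on other chromosomes, and for Ptx1 10.3% and 19.2%. On 3R 27 windows fell for Abd-B and 70 for Ptx1. Processing moved the counts of preferred windows both ways. With normexp background correction they were 233 for Abd-B, 25 for Antp and 2 for RpII140. With loess wntD had 349, and with the median of probes Abd-B had 8. Leaving out 1 replicate of the bait lowered the counts of the main run. Without replicate 1 they were 40 for Abd-B, 99 for Ptx1, 29 for wntD, 53 for CG5107 and 43 for RpII140. Without replicate 2 they were 20 for Abd-B, 12 for Antp, 37 for Ptx1, 216 for trh, 44 for CG5107, 50 for Crc and 17 for RpII140.

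On the bait's own arm, the 5 strongest preferred domains of Antp, Crc, wntD, CG5107 and Ptx1 all peaked within 5.25 Mb of the bait. Antp peaked at 3R 3.1-3.25 Mb (log2 3.17, SE 0.35, adjusted p = 8.7e-06) and also rose at 0.05-0.25 Mb, next to the start of the arm's coordinates (2.53, SE 0.32). Crc peaked at that same end, 0.05-0.35 Mb (2.92, SE 0.39, adjusted p = 1.8e-05), and at 1.05-1.75 Mb (2.88). The top wntD domain was 7.65-7.95 Mb (3.11, SE 0.31, adjusted p = 6.4e-07). RpII140, whose bait lies 0.85 Mb from that of wntD, also rose in this stretch (2.25, SE 0.31). On 3R CG5107 rose most at 22.55-23.05 Mb (2.76, SE 0.27) and Ptx1 at 27.2-27.55 Mb (2.37, SE 0.30). The trh windows on 3L were compared with 7 baits of the other arm and rose along much of it, with peaks at 1.70 Mb (3.75, SE 0.28), at 8.35 Mb (3.01, SE 0.26) and at 14.1 Mb (2.85, SE 0.31, adjusted p = 1.9e-07), 13.85 Mb from the bait. The highest Abd-B domain on its own arm was 3R 0.05-0.1 Mb (2.34, SE 0.30, adjusted p = 5.6e-05), 12.75 Mb from the bait, and RpII140 rose at 15.45-15.5 Mb (2.41, SE 0.33), 5.5 Mb away.

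On other chromosomes, where domains were chosen by size after their values were seen, the strongest trh domains lay at 2R 20.45-20.7 Mb (3.37, SE 0.35, adjusted p = 1.2e-07), at 2L 0-0.35 Mb (2.46, SE 0.33) and at X 1.95-2.05 Mb (2.08, SE 0.26). Ptx1 had its strongest at X 2.2-2.3 Mb (2.61, SE 0.33), 2R 9.2-9.3 Mb (2.54, SE 0.30) and X 17.6-17.65 Mb (2.51, SE 0.29), and Abd-B at 2R 0-0.1 Mb (2.39, SE 0.26) and 0.45-0.55 Mb (2.29, SE 0.30). The last 2 stem from low values in the other baits: the Abd-B signal itself was -0.05 ± 0.11 and 0.14 ± 0.40 (n = 2). The Ptx1 signal in its 3 domains was 0.67 ± 0.06, 1.00 ± 0.05 and 1.94 ± 0.49, so the first 2 also rest largely on low values elsewhere. The trh signal in its 2R domain was 3.64 ± 0.54. The counts for Abd-B and Ptx1 depended on the comparison: these baits share an array set, and against each other alone 4 and 5 windows rose. Within their sets Antp had 187, wntD 55 and RpII140 255.

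The contact between the Hox loci Abd-B and Antp, 10.2 Mb apart on 3R, was read from both sides. In the Abd-B map the Antp locus stood 1.38 ± 0.78 (n = 2) above the map's distance trend, at percentile 99.1 of the arm, and 2.13-fold above the other baits (log2 1.09, SE 0.43, adjusted p = 0.044). In the Antp map the Abd-B locus stood 0.68 ± 0.55 above the trend, at percentile 86.3, and 2.16-fold above the other baits (1.11, SE 0.37, adjusted p = 0.021). Without replicate 2 of every bait neither value passed the threshold, 0.38 (adjusted p = 0.697) and 0.79 (adjusted p = 0.484), and without replicate 1 the Abd-B locus in the Antp map did not (1.43, adjusted p = 0.081). Against the other baits, both also missed the threshold with loess (1.00 and 0.79), 20 kb windows (1.35 and 0.55) and the median of probes (1.21 and 1.24). The Abd-B locus in the Antp map further did so with normexp background correction (0.27) and dim probes left out (0.70), and with 20 kb windows it lay at -0.09 against the trend.

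The Ptx1 locus was also raised in the Abd-B map, 1.096 ± 0.21 above the trend (percentile 98.0) and 2.88-fold above the other baits (log2 1.52, SE 0.26, adjusted p = 5.7e-05) at a distance of 13.9 Mb. This value was 1.27 (adjusted p = 0.298) without replicate 2 of every bait. In the Ptx1 map the Antp locus, 24.1 Mb away, stood 0.84 ± 0.29 above the trend (percentile 96.8) but only 0.21 above the other baits (SE 0.43, adjusted p = 0.684), and the Abd-B locus lay at -0.30 against the trend. Over the 3 loci, the 6 contacts averaged 0.68 (SD 0.59) against -0.16 (SD 0.46) for the 36 other pairs of 3R baits. The difference of 0.84 was the highest of the 35 ways to choose 3 of the 7 baits on 3R (exact two-sided p = 0.0286, the smallest possible). It was 0.60 with 20 kb windows (exact p = 0.114), 0.55 without the distance correction (exact p = 0.229) and 0.08 with dim probes left out (exact p = 0.771).

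**Figure D2:**
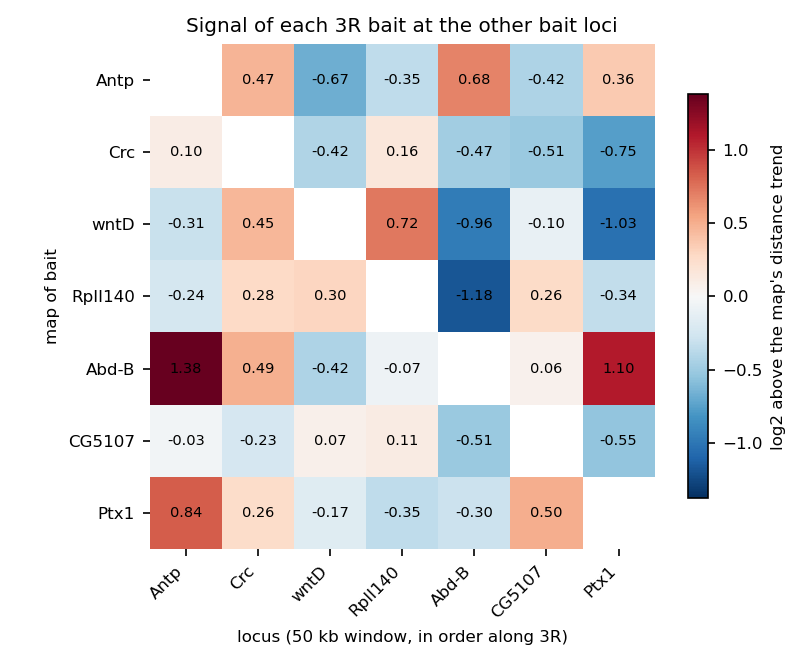
Mean log2 signal (2 replicates, colour scale and printed values) of each 3R bait's map, one line per bait, at the 50 kb windows of the other 3R bait loci, in order along the arm, after subtraction of the map's distance trend. The Abd-B map at the Antp locus (1.38) and at the Ptx1 locus (1.096) are the highest values, and RpII140 at the Abd-B locus (-1.18) is the lowest.

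The inversion In(3LR)sep exchanges the centromere-proximal 5.8 Mb of 3R, which holds Antp, with the centromere-proximal 17 Mb of 3L, so that Abd-B comes to share an arm with proximal 3L and Antp with distal 3L. The comparison asks whether contacts follow the new arms. In the inversion Abd-B gained contact with proximal 3L: relative to other chromosomes its signal there went from 0.06 ± 0.07 (n = 2) to 0.77 ± 0.31 (n = 2), a dye-adjusted rise of 0.73, or 1.66-fold (fry, adjusted p = 0.0019). Its signal on distal 3R rose from 0.91 ± 0.49 to 1.55 ± 0.30 (by 0.68, adjusted p = 0.043). Signal on proximal 3R, the part moved away from Abd-B, was 0.96 ± 0.49 in wild type and 0.06 ± 0.08 in the inversion, a difference of -0.81 that missed the threshold (adjusted p = 0.074). It passed with normexp background correction (-0.69), loess (-0.80), scaled arrays or dim probes left out (both -0.94), every array as a sample (-0.86), without the dimmest array (-0.93) and without wild type Abd-B replicate 1 (-1.16). Distal 3L differed by 0.25 (adjusted p = 0.119).

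Antp changed contacts on the complementary parts. On distal 3L its signal rose from -0.04 ± 0.004 to 1.00 ± 0.29 relative to other chromosomes, by 1.04 or 2.05-fold (adjusted p = 0.00031), and on distal 3R it fell from 0.69 ± 0.32 to -0.01 ± 0.02, by 0.71 (adjusted p = 0.043). Proximal 3R, which keeps Antp, differed by -0.68 (2.33 ± 0.94 against 1.65 ± 0.33, adjusted p = 0.106), by 0.30 with normexp background correction (adjusted p = 0.220) and by -1.95 with scaled arrays (adjusted p = 0.00031), so its direction depends on the processing. Proximal 3L differed by 0.13 (adjusted p = 0.393). It passed with loess (0.16, fry adjusted p = 0.021) and with dim probes left out (0.35, adjusted p = 0.026). With array-median centring it was -0.02, and 0.45 with normexp background correction (adjusted p = 0.0083). With arrays centred on the median of all probes, as planned, the rise of proximal 3L for Abd-B was 0.79 and that of distal 3L for Antp 0.88 (both adjusted p = 0.0185), distal 3R fell by 0.86 for Antp (adjusted p = 0.0498, and above 0.05 whichever of the 4 replicates was left out), and its Abd-B difference of 0.74 missed the threshold (adjusted p = 0.062). The planned Abd-B rise missed it with the median of probes (0.61), dim probes left out (0.72) and no dye term (0.70), and the Antp rise with no dye term (adjusted p = 0.176) and, at -0.26, with dim probes left out. With normexp background correction the Antp fall on distal 3R was -0.29 relative to other chromosomes (adjusted p = 0.334) and -0.023 with array-median centring (adjusted p = 0.969), and with the median of probes -0.51 and -0.56, neither past the threshold. The planned fall also missed it with 100 kb windows (adjusted p = 0.052), no dye term (0.178) and every array as a sample (0.051), and the relative one with loess (-0.62, adjusted p = 0.0505). The relative Abd-B rise on distal 3R missed it with normexp (0.57), loess (0.37), scaled arrays (0.46), the median of probes (0.83) and dim probes left out (0.36). With a replicate block, Antp on distal 3R missed the threshold under either centring (adjusted p = 0.072 and 0.068), as did Abd-B there relative to other chromosomes (0.66, adjusted p = 0.075). Without wild type Abd-B replicate 1 or inversion Abd-B replicate 1 the Abd-B rise on distal 3R was 0.34 and 0.43, past the threshold in neither case. The relative Antp fall on distal 3R missed it without wild type Antp replicate 2 (-0.53) and without inversion Antp replicate 1 (-0.78) or 2 (-0.64). The relative rises on proximal 3L for Abd-B and distal 3L for Antp passed whichever replicate was left out, but with array-median centring the former missed the threshold without wild type Abd-B replicate 1 (0.72) or inversion Abd-B replicate 1 (0.46), and the latter without wild type Antp replicate 2 (0.72) or inversion Antp replicate 2 (0.56). No stated slide or scan day held both genotypes of a bait, and 1 array of wild type Abd-B replicate 1 gives neither. Wild type RpII140, scanned on the same day as inversion Antp, stood at 0.04 ± 0.003 on distal 3L. An effect of that day on every map thus leaves the Antp rise there unexplained. Inversion Abd-B shared no stated scan day with a wild-type array. Yet the differences changed at the stated breakpoints: between the 2 Mb on either side, inversion minus wild type jumped by 1.00 (SE 0.18) on 3L and 1.53 (SE 0.23) on 3R for Abd-B, and by -0.93 (SE 0.18) and -1.13 (SE 0.13) for Antp. At 1185 positions on 2L, 2R and X the largest jump was 0.29 for Abd-B and 0.41 for Antp. How much of the shifts away from the breakpoints is due to batch cannot be read from this design.

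**Figure D3:**
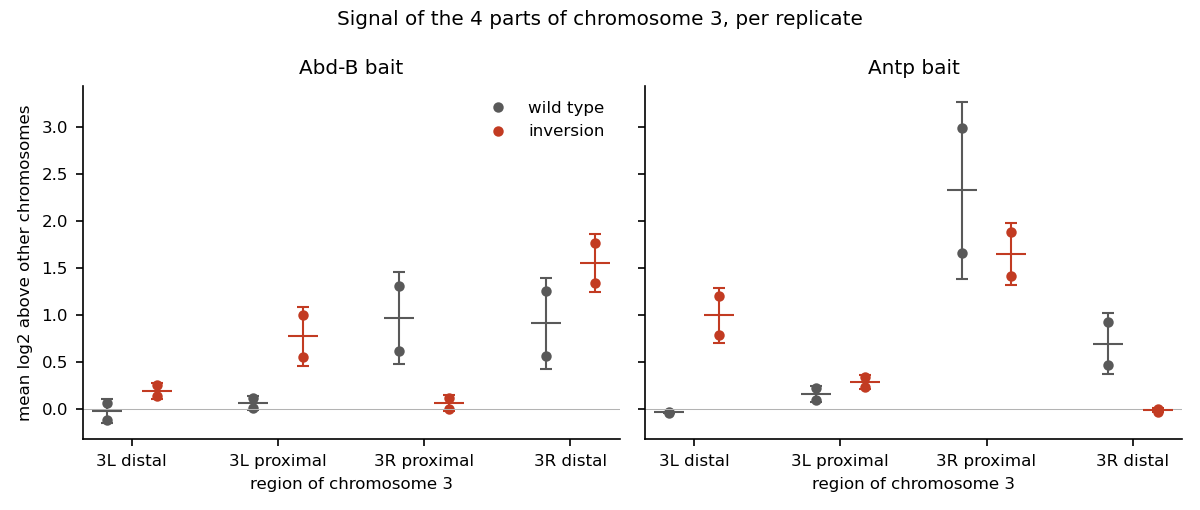
Mean log2 signal of the 4 parts of chromosome 3 (horizontal axis) above that of other chromosomes (vertical axis) for the Abd-B and Antp baits in wild type (grey) and inversion (red); points are the 2 replicates, horizontal marks means and bars SDs. Proximal 3L goes from 0.06 to 0.77 for Abd-B and distal 3L from -0.04 to 1.00 for Antp.

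**Figure D4:**
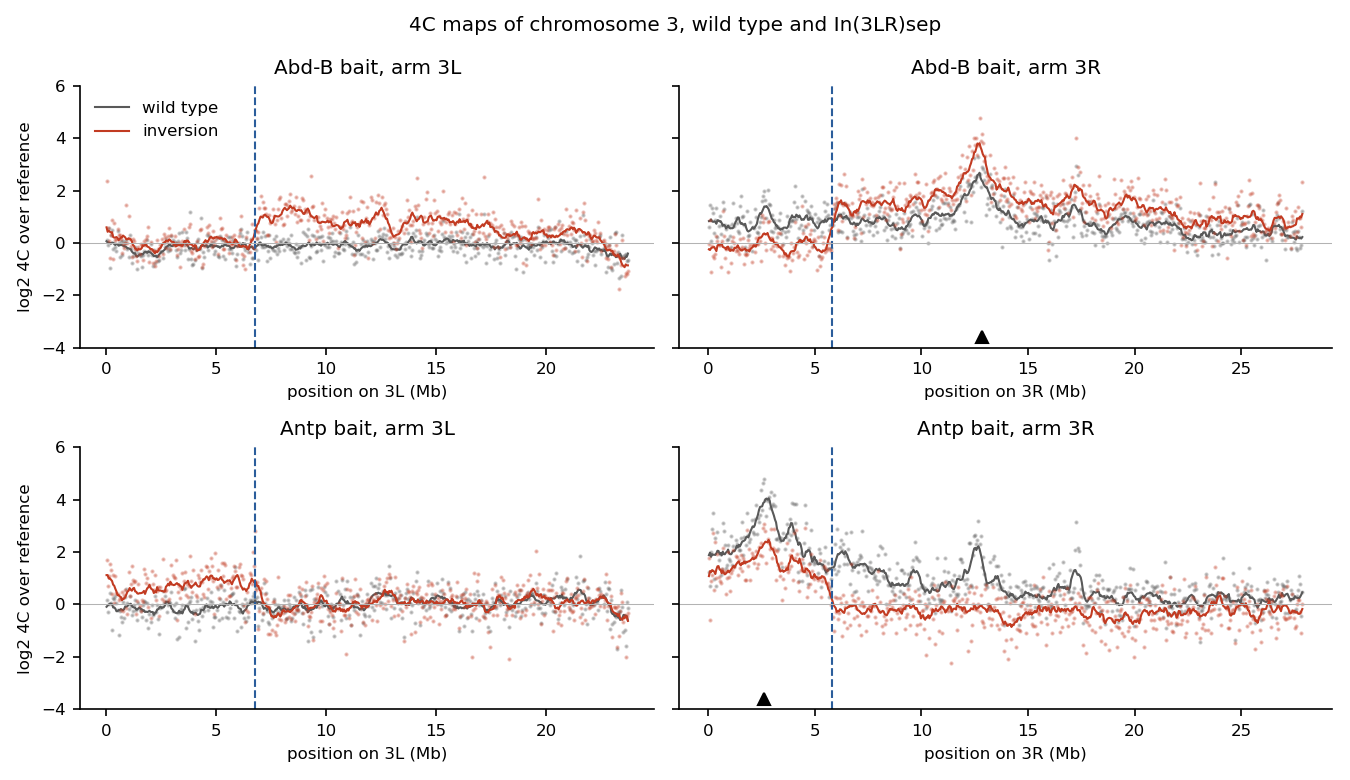
Log2 4C over reference along 3L and 3R (position in Mb) for the Abd-B and Antp baits in wild type (grey) and inversion (red); dots are 50 kb windows, means of 2 replicates, lines are running means over 11 windows, dashed lines mark the stated breakpoints at 6.76 Mb on 3L and 5.80 Mb on 3R, and triangles mark the bait. The red lines stand above the grey ones to the right of the 3L line for Abd-B and to the left of it for Antp.

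Whether the baits' shifts differed was tested directly. Relative to other chromosomes, the Abd-B shift exceeded the Antp shift by 0.60 on proximal 3L (adjusted p = 0.024) and by 1.35 on distal 3R (adjusted p = 0.013), and fell short of it on distal 3L, by -0.79 (adjusted p = 0.011). For proximal 3R the difference was -0.12 (adjusted p = 0.792), but -0.97 with normexp background correction (adjusted p = 0.015) and 1.04 with scaled arrays (adjusted p = 0.025). With array-median centring, distal 3R (1.56, adjusted p = 0.018) passed, and proximal 3L (0.82, adjusted p = 0.061) and distal 3L (-0.57, adjusted p = 0.188) did not. The 1.56 missed the threshold with normexp (0.50), loess (1.101), the median of probes (1.22) or no dye term (1.46). It also missed it without wild type Abd-B replicate 1 (1.20), wild type Antp replicate 2 (1.47), inversion Abd-B replicate 1 (1.22) or inversion Antp replicate 1 (1.46). By window, the Abd-B shift was above the Antp shift in 219 of 2315 windows and below it in 12, a balance that turned round with normexp background correction (39 above, 223 below) and shrank to 15 above and 3 below with loess. With normexp the relative differences on proximal 3L (0.39; 0.13 with dim probes left out) and distal 3R (0.83) missed the threshold, as did those on all 3 parts with the median of probes (0.54, 1.30 and -0.96 on distal 3L). Without wild type Antp replicate 2 the relative differences were 0.58 on proximal 3L and 1.17 on distal 3R, neither past the threshold, and the proximal 3L difference also missed it without wild type Abd-B replicate 1 (0.55) or inversion Antp replicate 1 (0.59) or 2 (0.61). The count of 219 was 55 without wild type Abd-B replicate 1, 64 without inversion Abd-B replicate 1, 70 without wild type Antp replicate 2 and 96 without inversion Antp replicate 1.

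The same contrasts were tested by window. For Abd-B 63 of 2334 windows rose and 5 fell, and 43 of the 63 lay on proximal 3L and 13 on distal 3R. The largest Abd-B rises were at 3L 9.25-9.35 Mb (log2 2.76, SE 0.46, adjusted p = 0.0042), 3L 0-0.05 Mb (2.28, SE 0.44), 3L 8.3-8.4 Mb (2.16, SE 0.35), 3L 7.85-7.95 Mb (2.11, SE 0.38) and X 1.55-1.6 Mb (2.02, SE 0.40). Of the 5 falls 4 were on proximal 3R, at 5.2, 5.05, 4 and 1.8 Mb (-1.67, -1.63, -1.61 and -1.60), and the last at X 7.55 Mb (-1.40). For Antp 42 windows rose, 30 of them on distal 3L, and 157 fell, 106 of them on distal 3R, whereas with normexp background correction 346 rose and 10 fell. Its rises included 3L 6.75-6.8 Mb at the breakpoint (2.62, SE 0.34, adjusted p = 8.3e-05), 4.95-5 Mb (2.44, SE 0.39) and 5.25-5.3 Mb (2.09, SE 0.37). Its largest falls were at 3R 5.8-6.7 Mb, which begins at the breakpoint (-3.28, SE 0.42), 17.2-17.45 Mb (-3.22, SE 0.46) and 12.15-12.95 Mb (-3.17, SE 0.44, adjusted p = 1.1e-04), the domain that contains the Abd-B locus. The 63 Abd-B rises were 0 with loess or dim probes left out, 3 with no dye term, 2 with 20 kb windows or the median of probes, 5 with arrays scaled to one spread, 97 with normexp background correction and 305 with centring on chromosomes other than 3. They were 0 without wild type Abd-B replicate 1 or inversion Abd-B replicate 1 and 147 without inversion Abd-B replicate 2, and the falls were 0 without any one of the 4 replicates (limma, 444 windows with an unadjusted p under 0.05 when all were kept). The Antp rises were 4 without wild type Antp replicate 2 and 6 without inversion Antp replicate 2, and the falls 29 without wild type Antp replicate 2, 63 without inversion Antp replicate 1 and 68 without inversion Antp replicate 2.

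The inversion places Abd-B and Antp on different arms. In the Antp map the signal at the Abd-B locus fell from 1.44 ± 1.06 to -0.64 ± 0.57 (n = 2 each), by 2.08 on the log2 scale (SE 0.49, limma adjusted p = 5.3e-04). In the Abd-B map the Antp locus was at 2.00 ± 1.28 in wild type and 0.95 ± 0.85 in the inversion, a difference of -0.92 (SE 0.56, limma adjusted p = 0.115). The latter was -1.82 without wild type Abd-B replicate 1 and -1.65 without inversion Abd-B replicate 1, both past the threshold, and -0.020 without wild type Abd-B replicate 2. The difference at the Antp locus in the Abd-B map passed the threshold with 20 kb windows (-1.89), 100 kb windows (-1.19) and scaled arrays (-1.33). It also passed with every array as a sample (-1.09) and without the dimmest array (-1.25). With normexp background correction the fall at the Abd-B locus in the Antp map was -0.47 (limma adjusted p = 0.0985). With array-median centring distal 3R, which holds the Abd-B locus, fell by 0.86 in the Antp map. Proximal 3R, which holds the Antp locus, differed by -0.75 in the Abd-B map (fry, adjusted p = 0.139). Whether either locus changed more than its region was not tested.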

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

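The region shifts centred on the other chromosomes, the comparison within array sets, the GC correction, the test over 35 choices of baits, the array-set test of contacts between bait loci, the scan-day test on RpII140, the jumps at the breakpoints, the scaling test of distal 3R and the direct comparison of the genotypes at the Abd-B windows were chosen after the results were seen.

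The shifts of Abd-B and Antp in the inversion differed from each other in a test of the difference, though not under every processing. The Abd-B shift exceeded the Antp shift on distal 3R by 1.56 with array-median centring, and relative to other chromosomes by 1.35 there and by 0.60 on proximal 3L, while on distal 3L it differed by -0.79. With array-median centring proximal 3L (0.82) and distal 3L (-0.57) missed the threshold. With the median of probes all 4 of the passing differences missed it (1.22, 1.30, 0.54 and -0.96, adjusted p from 0.058 to 0.105), and with normexp background correction all but distal 3L did (0.50, 0.83 and 0.39, adjusted p from 0.097 to 0.222). The proximal 3L difference was 0.13 with dim probes left out. The difference of 1.56 also missed the threshold with loess (1.101), no dye term (1.46) and in 4 of 8 runs without a replicate: wild type Abd-B 1 (1.20), wild type Antp 2 (1.47), inversion Abd-B 1 (1.22) and inversion Antp 1 (1.46). Against a GC trend of the probes, its removal left at least 92.9% of the rises on proximal 3L for Abd-B and distal 3L for Antp, and against the signal range of the arrays, scaling them to one spread left at least 94.5% with array-median centring, and 89.2% and 84.1% relative to other chromosomes. The differences between the baits passed with scaling too, at 1.59 with array-median centring and relative at 1.39, 0.64 and -0.62. Only for the relative Abd-B rise on distal 3R does scaling leave the range of the arrays open: it kept 67.2% (0.68 to 0.46, adjusted p = 0.190, as the rise itself shrank), while the Antp fall there went from -0.71 to -0.99. A scan-day effect on every map would raise distal 3L in wild type RpII140, scanned with inversion Antp, by about the Antp rise of 1.04, and it stood at 0.0411 ± 0.003 (n = 2). For Abd-B no stated scan day was shared, and the largest step on 2L, 2R or X was 0.553 of that on 3L, too large by itself to decide. An effect of array set, scan day or slide would not change at the breakpoints, where the Abd-B difference jumped by 0.997 (SE 0.18) on 3L and 1.53 (SE 0.23) on 3R, against at most 0.29 at 1185 positions on 2L, 2R and X and as much at 1.38% and 0.385% of positions on the same arm. It was -0.928 (SE 0.18) and -1.13 (SE 0.13) for Antp, against at most 0.41. All 4 jumps, the smallest 0.928 in size, have the direction of the new arrangement, which may explain them, as a hypothesis found and tested on the same data. The test of arrangement written in advance counted a best single split over 3 Mb from a breakpoint against it. In 3 of the 4 profiles the split lay at most 0.145 Mb off, and for Antp on 3R 8.65 Mb off, but a single split misses a breakpoint where the level changes more than once, as the jump of -1.13 there shows. A share of batch in the shifts away from the breakpoints stays open.

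Abd-B and Ptx1 stood above the other baits mostly on other chromosomes, and both maps come from one array set. The 89 Abd-B windows kept 85.1% of their height in the inversion Abd-B arrays, which belong to another set. That share does not decide on the array set, since the height is taken against the same baits, which were low in these windows (-1.18 against -0.27 in the others). The genotypes compared directly differed there by a mean of 0.174 of 1.17 (SE 0.046 over the 89 windows, which are not independent replicates). By its size this counts against an effect on the wild-type Abd-B and Ptx1 arrays alone for Abd-B. Its spread over the 2 replicates per genotype was not tested. A low signal in the sets of the other 6 baits and a difference between baits cannot be told apart, as no set holds both kinds. With the GC trend removed 304 windows passed against 342, or 88.9%, and with dim probes left out 217 of 482 tested windows passed against 342 of 2642, a share of 348% of that with all probes. The filter keeps brighter windows, and called windows were brighter in the reference channel (7.95 against 7.54 log2), so the size of that ratio says little, but windows without dim probes still passed. Compared within their array set, that is with each other alone, 1 of 2642 passed. Measured against the 6 baits of other sets, the Ptx1 map held 87.5% of the height at the Abd-B windows and wild type Abd-B 52.9% of that at the 253 Ptx1 windows, where inversion Abd-B, of another set, held 68.4%. Of the 89 and 253 windows 57 were called in both. No biological explanation was tested.

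The Abd-B, Antp and Ptx1 loci stood above the distance trend in each other's maps in 5 of 6 cases. If some loci or maps were high throughout, the difference would vanish once the mean of each map and locus is removed, and 0.63 of 0.84 remained (75.0%, exact two-sided p = 0.0286, the smallest possible). The 4 contacts between baits of different sets averaged 0.81 (SE 0.21 over contacts, which share loci and maps). This does not decide on the array set. The Antp locus stood above the trend in both maps of the Abd-B and Ptx1 set (1.38 and 0.84). In the maps of the remaining 3R baits it ran only from -0.31 (wntD) to 0.10 (Crc). In the Antp map, of another set, the Abd-B and Ptx1 loci stood at 0.68 and 0.36. Contact among Polycomb targets may explain the pattern as a hypothesis found and tested on the same data, and it did not hold with dim probes left out (0.08) or with 20 kb windows (0.60, exact p = 0.114). The labels do not give this class, and wntD was counted outside it without a check. The wntD map lay below the trend at the Abd-B, Antp and Ptx1 loci (-0.96, -0.31 and -1.03). The wntD locus lay below it in their maps (-0.42, -0.67 and -0.17). Were wntD a target, these values would count against the hypothesis. The trh locus, a Polycomb target on the other arm that the test leaves out, went both ways. Against the other baits it was high in the Ptx1 map (2.36, limma adjusted p = 3.6e-05) and the Abd-B map (1.42, adjusted p = 0.005), which share an array set. The signal itself was 1.29 ± 0.05 and 0.48 ± 1.08 (n = 2). In the maps of the other 3R baits the trh locus was low, from -1.98 (RpII140) to -0.59 (Crc). The Abd-B height rests largely on that, and the Ptx1 height in part. Against the other baits it stood at -0.27 in the Antp map (adjusted p = 0.573). In the trh map the Abd-B, Antp and Ptx1 loci stood at -1.01, -0.59 and -0.29. These values decide nothing, since the baits compared with lie on 3R, the arm of these loci. The remaining 3R bait loci were low in the trh map too, from -1.99 (Crc) to -0.48 (CG5107).

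The lambda phage probes, which no comparison uses, were above background for a median of 20.3% of probes in the 4C channel against 18.6% in the reference channel, and no explanation was tested.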

How the results depend on the processing

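The correction for GC, the run without the dimmest array, the comparison within array sets and the shifts relative to other chromosomes, written (relative), were chosen after the data were seen.

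The same-arm excess and the fall with distance kept their direction and passed the threshold under every alternative run. So did the relative rises of proximal 3L for Abd-B (0.48 to 0.99) and of distal 3L for Antp (0.85 to 1.20), leaving out single replicates included. Of 1701 values of 60 named domains under the alternatives, 1584 kept their side of the threshold, 117 no longer passed and 0 changed direction (limma). The domains were chosen as the largest passing peaks of these data. Many of the runs left out a replicate of a bait other than the domain's own. This stability was thus partly fixed in advance. A zone of 200 kb, slide as a random block and windows near the breakpoints kept changed no direction or call. For the values that follow the cause was not tested, except that the dim-probe filter leaves 471 of 2353 windows (29 of 125 on distal 3L).

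With normexp background correction, the windows above the other baits numbered 233 for Abd-B, 25 for Antp, 59 for CG5107 and 2 for RpII140. The windows numbered 97 higher in the inversion for Abd-B, 32 lower in the inversion for Abd-B, 346 higher in the inversion for Antp, 10 lower in the inversion for Antp, 39 with an Abd-B shift above the Antp shift and 223 with an Abd-B shift below the Antp shift. Abd-B shifted by -0.76 on 3R proximal, -0.066 on other chromosomes, -0.69 on 3R proximal (relative) and 0.57 on 3R distal (relative). Antp shifted by 0.45 on 3L proximal, 0.56 on 3R proximal, -0.023 on 3R distal, 0.26 on other chromosomes, 0.30 on 3R proximal (relative) and -0.29 on 3R distal (relative). Subtracting the Antp shift from that of Abd-B gave -1.06 on 3L distal, -1.30 on 3R proximal, 0.50 on 3R distal, -0.33 on other chromosomes, 0.39 on 3L proximal (relative), -0.97 on 3R proximal (relative) and 0.83 on 3R distal (relative). The value was 0.27 for the Abd-B locus in the Antp map above the other baits, 0.0043 for the Abd-B locus in the Ptx1 map above the other baits, 0.025 for the Abd-B locus in the Ptx1 map above the distance trend, -0.44 for the Ptx1 locus in the Antp map above the other baits, -0.21 for the Ptx1 locus in the Antp map above the distance trend and -0.47 for the Abd-B locus in the Antp map inversion minus wild type. With loess within arrays, the windows above the other baits numbered 38 for Antp, 180 for Ptx1, 310 for trh, 349 for wntD, 197 for CG5107 and 63 for Crc. The windows numbered 0 higher in the inversion for Abd-B, 0 lower in the inversion for Abd-B, 99 lower in the inversion for Antp, 15 with an Abd-B shift above the Antp shift and 3 with an Abd-B shift below the Antp shift. Abd-B shifted by -0.90 on 3R proximal, -0.10 on other chromosomes, -0.80 on 3R proximal (relative) and 0.37 on 3R distal (relative). Antp shifted by 0.16 on 3L proximal (relative) and -0.62 on 3R distal (relative). The Abd-B minus Antp difference was -0.69 on 3L distal, 0.53 on 3L proximal, -0.29 on 3R proximal and 1.101 on 3R distal. The value was 1.00 for the Antp locus in the Abd-B map above the other baits, 0.79 for the Abd-B locus in the Antp map above the other baits and -0.25 for the Ptx1 locus in the Antp map above the other baits. With centring on chromosomes other than 3, the windows numbered 305 higher in the inversion for Abd-B, 3 lower in the inversion for Abd-B and 359 with an Abd-B shift above the Antp shift. Abd-B shifted by 1.05 on 3R distal and 0.37 on other chromosomes. Antp shifted by 0.0035 on 3L proximal. Subtracting the Antp shift from that of Abd-B gave 1.098 on 3L proximal and 0.49 on other chromosomes. With arrays scaled to one spread, the windows above the other baits numbered 212 for Antp and 195 for wntD. The windows numbered 5 higher in the inversion for Abd-B, 0 lower in the inversion for Abd-B and 237 lower in the inversion for Antp. Abd-B shifted by -0.94 on 3R proximal (relative) and 0.46 on 3R distal (relative). Antp shifted by -1.99 on 3R proximal and -1.95 on 3R proximal (relative). The Abd-B minus Antp difference was 0.84 on 3L proximal, 1.24 on 3R proximal and 1.04 on 3R proximal (relative). The value was -1.33 for the Antp locus in the Abd-B map inversion minus wild type. With 20 kb windows, the windows above the other baits numbered 269 for Abd-B, 828 for trh and 139 for RpII140. The windows numbered 2 higher in the inversion for Abd-B, 0 lower in the inversion for Abd-B, 104 with an Abd-B shift above the Antp shift and 7 with an Abd-B shift below the Antp shift. The value was 1.35 for the Antp locus in the Abd-B map above the other baits, 0.55 for the Abd-B locus in the Antp map above the other baits, -0.088 for the Abd-B locus in the Antp map above the distance trend, 0.15 for the Abd-B locus in the Ptx1 map above the other baits, -0.16 for the Antp locus in the Ptx1 map above the other baits and -1.89 for the Antp locus in the Abd-B map inversion minus wild type. The contacts among the Abd-B, Antp and Ptx1 loci differed from the others by 0.60. The other arm minus other chromosomes was 0.10. In 100 kb windows, the windows above the other baits numbered 46 for Abd-B, 67 for Antp, 200 for Ptx1, 278 for trh, 61 for wntD, 60 for CG5107, 155 for Crc and 45 for RpII140. The windows numbered 7 with an Abd-B shift below the Antp shift. Antp shifted by -0.86 on 3R distal. The value was -0.15 for the Ptx1 locus in the Antp map above the other baits and -1.19 for the Antp locus in the Abd-B map inversion minus wild type.

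With the median of probes, the windows above the other baits numbered 8 for Abd-B, 52 for Antp, 70 for Ptx1, 36 for wntD, 166 for Crc and 46 for RpII140. The windows numbered 2 higher in the inversion for Abd-B, 0 lower in the inversion for Abd-B, 19 higher in the inversion for Antp, 27 lower in the inversion for Antp, 23 with an Abd-B shift above the Antp shift and 7 with an Abd-B shift below the Antp shift. Abd-B shifted by 0.61 on 3L proximal, -0.13 on other chromosomes and 0.83 on 3R distal (relative). Antp shifted by 0.15 on 3L proximal, -0.56 on 3R distal and -0.51 on 3R distal (relative). Subtracting the Antp shift from that of Abd-B gave -0.26 on 3R proximal, 1.22 on 3R distal, -0.075 on other chromosomes, -0.96 on 3L distal (relative), 0.54 on 3L proximal (relative) and 1.30 on 3R distal (relative). The value was 1.21 for the Antp locus in the Abd-B map above the other baits, 1.24 for the Abd-B locus in the Antp map above the other baits and -0.19 for the Ptx1 locus in the Antp map above the other baits. With dim probes left out, the windows above the other baits numbered 42 for trh, 8 for wntD, 9 for CG5107, 55 for Crc and 7 for RpII140. The windows numbered 0 higher in the inversion for Abd-B, 0 lower in the inversion for Abd-B, 1 higher in the inversion for Antp, 141 with an Abd-B shift above the Antp shift and 0 with an Abd-B shift below the Antp shift. Abd-B shifted by 0.72 on 3L proximal, -0.94 on 3R proximal (relative) and 0.36 on 3R distal (relative). Antp shifted by -0.26 on 3L distal, -1.36 on 3R proximal, -1.13 on other chromosomes and 0.35 on 3L proximal (relative). The Abd-B minus Antp difference was 0.79 on 3L distal, 1.50 on 3L proximal, 1.37 on other chromosomes and 0.13 on 3L proximal (relative). The value was 0.70 for the Abd-B locus in the Antp map above the other baits, -0.17 for the Abd-B locus in the Antp map above the distance trend, 0.29 for the Abd-B locus in the Ptx1 map above the other baits, -0.35 for the Ptx1 locus in the Antp map above the other baits and -0.051 for the Ptx1 locus in the Antp map above the distance trend. The contacts among the Abd-B, Antp and Ptx1 loci differed from the others by 0.078. With no dye term, the windows above the other baits numbered 55 for Abd-B, 66 for Antp, 172 for Ptx1, 65 for wntD, 171 for Crc and 52 for RpII140. The windows numbered 3 higher in the inversion for Abd-B, 0 lower in the inversion for Abd-B, 14 higher in the inversion for Antp, 67 lower in the inversion for Antp, 49 with an Abd-B shift above the Antp shift and 3 with an Abd-B shift below the Antp shift. Abd-B shifted by 0.70 on 3L proximal and -0.0099 on other chromosomes. Antp shifted by 0.88 on 3L distal and -0.86 on 3R distal. Subtracting the Antp shift from that of Abd-B gave -0.074 on 3R proximal and 1.46 on 3R distal. With a replicate block, the windows numbered 14 higher in the inversion for Abd-B and 1 lower in the inversion for Abd-B. Abd-B shifted by 0.66 on 3R distal (relative). Antp shifted by -0.86 on 3R distal and -0.71 on 3R distal (relative). With every array as a sample, the windows numbered 104 higher in the inversion for Abd-B and 21 lower in the inversion for Abd-B. Abd-B shifted by -0.86 on 3R proximal (relative). Antp shifted by -0.86 on 3R distal. The value was -1.09 for the Antp locus in the Abd-B map inversion minus wild type. With a 1000 kb zone around the bait, the windows above the other baits numbered 76 for Antp, 67 for wntD and 53 for RpII140. With no distance correction, the value was -0.40 for the Ptx1 locus in the Antp map above the distance trend. The contacts among the Abd-B, Antp and Ptx1 loci differed from the others by 0.55. At a 10% false discovery rate, the windows numbered 122 higher in the inversion for Abd-B, 19 lower in the inversion for Abd-B and 68 higher in the inversion for Antp. Within the same array set only, the windows above the other baits numbered 4 for Abd-B, 187 for Antp, 5 for Ptx1, 55 for wntD and 255 for RpII140. With the GC trend removed, the windows numbered 9 lower in the inversion for Abd-B. Abd-B shifted by -0.00081 on other chromosomes. Antp shifted by 0.016 on 3L proximal. The Abd-B minus Antp difference was -0.016 on 3R proximal. Without the dimmest array, the windows above the other baits numbered 243 for Abd-B. The windows numbered 24 lower in the inversion for Abd-B and 20 with an Abd-B shift below the Antp shift. Abd-B shifted by -0.97 on 3R proximal, -0.042 on other chromosomes and -0.93 on 3R proximal (relative). Subtracting the Antp shift from that of Abd-B gave -0.13 on 3R proximal. The value was -1.25 for the Antp locus in the Abd-B map inversion minus wild type. Without the Ptx1 bait, the other arm minus other chromosomes was 0.10.

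Leaving out each replicate in turn gave these ranges, with a lone remaining replicate assumed to vary like the other groups. The windows above the other baits numbered 20 to 141 for Abd-B, 12 to 129 for Antp, 37 to 340 for Ptx1, 216 to 503 for trh, 29 to 121 for wntD, 44 to 104 for CG5107, 50 to 284 for Crc and 17 to 96 for RpII140. The inversion windows numbered 0 to 147 higher for Abd-B and 4 to 47 higher for Antp, 0 throughout lower for Abd-B and 29 to 148 lower for Antp and 55 to 327 with an Abd-B shift above the Antp shift and 2 to 19 with an Abd-B shift below the Antp shift (limma, 444 and 535 with an unadjusted p under 0.05 for Abd-B and Antp when all were kept). The Abd-B shifts ran from 0.46 to 1.16 on 3L proximal, 0.37 to 1.11 on 3R distal, -0.034 to 0.16 on other chromosomes, -1.16 to -0.46 on 3R proximal (relative) and 0.34 to 1.02 on 3R distal (relative). The Antp shifts ran from 0.56 to 1.21 on 3L distal, -0.20 to 0.15 on 3L proximal, -1.31 to -0.36 on 3R proximal, -0.96 to -0.76 on 3R distal, -0.31 to 0.012 on other chromosomes, -1.24 to -0.13 on 3R proximal (relative) and -0.89 to -0.53 on 3R distal (relative). The Abd-B minus Antp differences ran from 0.48 to 1.18 on 3L proximal, -0.42 to 0.54 on 3R proximal, 1.20 to 1.94 on 3R distal, 0.36 to 0.86 on 3L proximal (relative), -0.71 to 0.39 on 3R proximal (relative) and 1.01 to 1.70 on 3R distal (relative). The locus values ran from 0.38 to 1.80 for the Antp locus in the Abd-B map above the other baits, 0.79 to 1.43 for the Abd-B locus in the Antp map above the other baits, -0.77 to 0.18 for the Abd-B locus in the Ptx1 map above the other baits and -1.82 to -0.020 for the Antp locus in the Abd-B map inversion minus wild type.

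Alternatives for gene lists, the class of wntD among them, were not run, since no gene annotation in the array's build was used. Signal over background limits all of this: on the dimmest array 24.4% of genomic probes were well above background in the 4C channel.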

Other observations

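The 2 tests of chromosome ends and that of nearness to the centromere were chosen after the results were seen, and that of relative position before.

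The trh bait lies 0.261 Mb from the free end of 3L, and a candidate explanation for its contacts on other chromosomes is contact between chromosome ends. Windows within 500 kb of the free ends of X, 2L, 2R and 3R stood 1.22 ± 0.22 (n = 2) above the rest of those arms in the trh map, 1.18 more than in the other baits' maps (fry, adjusted p = 1.3e-06 over 8 baits). These windows include the trh domains on 2R and 2L that prompted the test, which therefore partly restates them. On X and 3R, whose ends hold none of the 3 strongest trh domains, the ends stood 1.05 ± 0.22 above the rest, 1.105 more than in the other baits' maps (adjusted p = 2.2e-05). Both contrasts include 3R, the own arm of all the other baits, where their signal falls with distance. Part of each contrast can stem from that. In the trh map 6 of 10 windows at the end of X passed and 1 of 10 at the end of 3R. The excess was 1.11 on X, 1.42 on 2L, 1.37 on 2R and 0.99 on 3R. In the other baits' maps the ends stood from -0.02 (Antp) to 0.40 (CG5107) above the rest. These values cover 30 windows against 40 for trh, since 3R, the arm of these baits, is left out. At the ends of X and 3L (10 windows) they ran from 0.03 (Antp) to 0.77 (CG5107). The next nearest bait to its own end, Ptx1 at 1.17 Mb, had an excess of 0.09 over the other baits (fry, adjusted p = 0.289). Those baits include trh, which lowers this excess. On X and 3L CG5107, at 6.52 Mb, had one of 0.45 (fry, adjusted p = 0.019). The ends stood highest above the rest for trh (1.22), CG5107 (0.40) and Ptx1 (0.37), the baits nearest their own ends. Their order was not that of nearness, and Crc at 22.4 Mb (0.26) stood above Abd-B at 15.1 Mb (0.02). A relation with nearness over the baits was not tested.

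Signal on other chromosomes may depend on a like position between centromere and chromosome end. Relative to the other baits it fell with the difference in relative position for 8 of 8 baits, with a mean slope of -0.23 (SD 0.11, exact two-sided sign-flip p = 0.0078, the smallest possible). The 8 slopes are not independent, since each bait is measured against the others. A high signal of 1 bait lowers the others in the same windows, and trh had the steepest slope (-0.46). The count of 8 and the p-value thus overstate the evidence.

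Signal on the other arm of chromosome 3 may depend on the nearness of the bait to the centromere. Over the 8 baits it was lower for baits farther from it (Spearman's rho -0.905, exact two-sided permutation p = 0.00456; Pearson's r -0.69, exact permutation p = 0.0302; 1 relation computed). Without Ptx1 and trh, the baits farthest from the median distance, r was -0.64, and without Crc, the bait with the highest value, it was -0.88. The 8 baits fall into 3 array sets of at most 4 baits, too few for a correlation within a set. In the set of 4 the value was 0.10 for Antp (2.62 Mb from the centromere end of the arm), 0.37 for Crc (5.47 Mb), 0.09 for wntD (9.12 Mb) and -0.03 for CG5107 (21.4 Mb), so the nearest bait was not the highest. Along 3L the Crc map stood 0.61 ± 0.20 (n = 2) above other chromosomes in the 5 Mb nearest the centromere and 0.09 ± 0.01 in windows 20 Mb or more from it.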
